A study of Bos taurus with 8 samples.

How the data were processed

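Transcripts of bovine blastocysts grown with or without buthionine sulfoximine (BSO) were measured on 8 dual-colour arrays, each of which held BSO-treated embryos in one dye and control embryos in the other. Per the labels' protocols, RNA of pooled blastocysts was extracted, amplified over a pair of T7 polymerase rounds and labelled chemically with Cy3 or Cy5. Per the labels, BSO was in Cy5 and control in Cy3 on 4 arrays, and the dyes were exchanged on the other 4. The labels name slides 114 and 115, with 2 arrays each, and slide 25, with 4 arrays.

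For each array, the deposited scanner output held the mean raw intensity of every spot and of its local background at 532 nm, which excites Cy3, and at 635 nm, which excites Cy5. Per the file headers these intensity values were raw, and no subtraction or normalization had been applied to them. The image software was not given in the sources used here. A second deposited table held 1 value per probe and array on a log2 scale. The submitters' processing notes named limma without a version, and the background correction and normalization behind these log2 values were not given in the sources used here. Set against the scanner values, the deposited log2 values were ratios of BSO over control on all 8 arrays, with array medians between 0.0011 and 0.013. Over probes, they correlated with the normalized ratios computed here at 0.889 (replicate 3, BSO in Cy3) to 0.989.

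Scanner values were processed in R 4.3.3 with limma 3.58.1 and jsonlite 2.0.0. The local background was corrected with the normexp method and an offset of 50, because plain subtraction left 96 probes without a logarithm. Ratios were normalized within each array by loess, with control spots at weight 0, and every array was then turned to log2 of BSO over control. Of 45220 spots per array, 43794 were gene probes and 153 were negative controls, and no probe was spotted more than once. A probe was kept if its spot was brighter than the 95th percentile of the negative controls on at least 4 of the 8 arrays, in the BSO channel or in the control channel. This left 36995 probes. Of these, 23543 passed that limit in both channels on all 8 arrays.

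Gene symbols came from the platform annotation, in which 21790 probes had 1 symbol, 0 had several and 22004 were unnamed. Of the kept probes, 18926 were named, for 13678 genes, and 18069 were unnamed here. Symbols were updated through a table of RefSeq genes on the ARS-UCD2.0 assembly, which was used for names only. In it, 17350 kept probes had a current symbol, 1360 had an older symbol that was updated and 216 had a symbol that was not found and was kept. Neither the annotation nor the files named a genome build, so no coordinates are given. Where a gene had several kept probes, the brightest stood for it in the gene lists.

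The design gave 4 pools per treatment on 8 arrays, so each pool lay on more than 1 array, but the labels did not say which arrays shared pools. Arrays of opposite dye orientation were therefore matched by rule. Of the 24 possible matchings, the one with the highest summed correlation of deviations from the mean of each orientation was taken. Its sum was 2.98, against 1.44 for the second, and its correlations were 0.657 to 0.843, while the highest between unmatched arrays was -0.049. Deviations within an orientation sum to 0 for each probe, so positive matched values push the others toward negative ones. The gap between them is thus partly built in. The matching was inferred from the data, and it equalled the order of arrays within slides. The 2 arrays of a matched pair were averaged to 1 replicate, which gave 4 replicates in which a dye effect cancels. Replicates 1 and 2 lay on slides 114 and 115, and replicates 3 and 4 on slide 25.

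The mean of the 4 replicates was tested against 0 with limma (lmFit and eBayes), with Benjamini-Hochberg adjustment over probes and a threshold of 0.05. The normalized ratio shows unequal change between genes, not a change in total RNA. Dye effects were counted on the 8 arrays with a treatment and a dye term, and the BSO effect was compared between the 2 slide sets. From general knowledge of glutathione depletion and blastocyst biology, 26 gene lists were fixed. The lists, the matching rule, the tests and the rule for naming genes were set before the data were examined. Of the lists, 25 were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and with an estimated correlation and with fry as alternatives. The list of mitochondrially encoded genes had no gene with a probe symbol and was not tested. Each list was also set against 10000 random lists of the same size matched on brightness.

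The rule for naming genes took the largest log2 ratios past the threshold in each direction, filled up to 8 with the largest ratios at unadjusted p under 0.01 and the same sign in all 4 replicates. Loci without a descriptive symbol were skipped. The rule also named an 18-gene panel of glutathione and antioxidant genes and up to 4 members of each list with the lowest p. Of the panel, 17 genes are given and the rest was not analysed here.

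Alternatives covered the background correction, the normalization, the filter on dim probes, the matching and averaging of arrays, the slides, array weights, the replicates left out in turn, the deposited log2 values, the variance prior, the threshold and the set test. A stricter filter, a background taken from negative controls, a threshold of 0.10 and the removal of each replicate's dye profile were added after seeing the data. The steps were tested on simulated data built on the 36995 probes, with 200 probes changed. The array matching was recovered. The simulated spreads within and between pairs came from the matching inferred here, so this is no check of that matching. Of probes changed 1.5-fold, 92% had an unadjusted p under 0.05 in the right direction and 46 of 100 passed the adjusted threshold. Of probes changed 2-fold, 99% and 79 of 100 did. The changed probes were drawn at random from all kept probes, dim ones included, each at its own spread. By contrast, the 8 genes named for the lowest ratios, all more than 2-fold lower, had replicate SDs of 0.34 to 0.75 and did not pass. The simulated shares may therefore be too high for such probes. Of unchanged probes, 5.51% had an unadjusted p under 0.05 and 3 passed the adjusted threshold. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

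Median spot intensity per array was 163 to 276 in Cy3 and 125 to 228 in Cy5, over local backgrounds of 16.2 to 19.5 and 30.4 to 51.0. Negative-control spots had medians of 115 to 223 in Cy3 and 88.9 to 186 in Cy5, far above the local background, so normexp left signal in dim spots that was not transcript. The ratios of dim probes are therefore smaller than the true ratios. Between 71.1% and 83.2% of probes were brighter than the negative-control limit in the BSO channel, and between 67.9% and 87.0% in the control channel. The number of arrays limits the precision of every value.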

Results

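Bovine embryos produced in vitro were cultured with or without BSO, and the blastocysts were compared by array. BSO blocks glutamate-cysteine ligase, the first enzyme of glutathione synthesis, so the comparison asks how blastocyst transcripts differ when embryos develop with that block. Glutathione levels were not among the values used here, so its depletion is assumed. Per the labels, 0.4 mM BSO was present from day 3 to day 5 of culture and 0.01 mM from day 5 to day 7. Blastocysts were collected 196 h after fertilization in pools of 10, with 4 pools per treatment. The 8 arrays of the EmbryoGENE bovine platform held 4 arrays of each dye orientation. They were averaged to 4 replicates, each with 1 BSO and 1 control pool, and values are log2 ratios of BSO over control unless stated. The labels do not say whether the pools came from separate cultures or animals, so p-values measure the spread between pools, which may be technical.

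In BSO blastocysts, markers of trophectoderm, the outer epithelium that forms the placenta, were lower as a group with camera at its preset correlation, and so were transcripts of ribosomal proteins. Both calls were lost with an estimated inter-gene correlation, at a camera adjusted p of 0.800 for each. Before adjustment that p was 0.0593 for trophectoderm markers and 0.444 for ribosomal proteins. Camera then also rests on the few residual degrees of freedom of 4 replicates. The loss therefore cannot be put down to gene correlation alone. Among genes with a descriptive symbol, each taken at its brightest probe, that had an unadjusted p under 0.01 and the same sign in all 4 replicates, the lowest ratios were those of PLCH1, KRT19, TPI1 and SMAD6, at 2.24-fold to 2.43-fold lower, and the highest were those of ENPEP, HIST1H2BN and HNRNPH2, at 1.85-fold to 1.98-fold higher. No single probe reached significance: 0 of 36995 probes passed an adjusted p of 0.05 with limma, and the lowest adjusted p was 0.0514. At an unadjusted p under 0.05 there were 8297 probes, 3206 higher and 5091 lower, against 1850 expected by chance. With at least a 1.5-fold difference as well, there were 148 higher and 473 lower. The same sign in all 4 replicates was found for 34.4% of probes, against 12.5% by chance. The count of 0 depended on the processing. With all 8 arrays fitted and the matched pair as a replicate block, 1408 probes were higher and 2540 lower at the same threshold. With matched arrays averaged, 468 passed without background correction, 356 with array weights and 91 without the filter on dim probes. Over the 24 possible matchings of arrays the median count was 5096, and the matching used gave the lowest. Every other matching averages some arrays whose deviations correlate at -0.049 or below. This shrinks the spread between averages, so those counts are not equally valid outcomes. After median centring in place of loess, 49.0% of the probes at an unadjusted p under 0.05 were higher, against 38.6% with loess.

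None of the 8 genes with the highest ratios, chosen for an unadjusted p under 0.01 and the same sign in all 4 replicates, passed the adjusted threshold. ENPEP, a membrane aminopeptidase, was at 0.98 ± 0.17 (limma SE, n = 4), or 1.98-fold, with a limma adjusted p of 0.080. GCSH, the lipoyl-carrying H protein of the mitochondrial glycine cleavage system, was at 0.87 ± 0.15, and its 2 other probes were at 1.02 and 1.05. FDX1, a mitochondrial ferredoxin that passes electrons to steroid-synthesizing cytochromes, was at 0.87 ± 0.09 with an adjusted p of 0.057, the lowest of the 8. TFRC, the transferrin receptor that takes up iron, was at 0.82 ± 0.15. HNRNPH2, an RNA-binding protein, was at 0.89 ± 0.19, and the sorting nexin SNX18 at 0.78 ± 0.14, with 1 of its 2 other probes at 0.28 and the other at -0.035. The histone gene HIST1H2BN was at 0.95 ± 0.21, with replicate 3 at 0.15 and the rest at 1.15 to 1.29. ASB3 was at 0.84 ± 0.09 on its brightest probe, while its 3 other probes lay between -0.027 and 0.10.

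The 8 genes with the lowest ratios, chosen under the same conditions, did not pass the adjusted threshold either. PLCH1, a phospholipase C, was at -1.28 ± 0.30 (limma SE, n = 4), or 2.43-fold lower, with a limma adjusted p of 0.112. KRT19, a keratin of simple epithelia and of trophectoderm, was at -1.21 ± 0.21 with an adjusted p of 0.082. TPI1, the triosephosphate isomerase of glycolysis, was at -1.17 ± 0.17 with an adjusted p of 0.070. IFNT, the interferon by which the ruminant trophoblast signals pregnancy, was at -1.12 ± 0.26, and it belongs to a multigene family whose members a probe may not tell apart. ARRB2, the beta-arrestin that shuts off G-protein-coupled receptors, was at -1.14 ± 0.22. SMAD6, an inhibitor of BMP signalling, was at -1.17 ± 0.14, but its mean was -2.23 on arrays with BSO in Cy5 and -0.098 on arrays with BSO in Cy3. Gaps of the same kind were found for MIR296, a microRNA gene at -1.12 ± 0.23, with -1.82 and -0.43, and for PLCH1, with -1.88 and -0.68, ARRB2, with -1.62 and -0.67, and HAX1, with -1.58 and -0.67. HAX1, which protects cells from apoptosis, was at -1.12 ± 0.18 on its brightest probe, and its 2 other probes were at -0.14 and -0.038. All 16 genes passed in the fit with the matched pair as a replicate block, at adjusted p of 0.00237 to 0.0111. They were chosen from the same data, so this is no separate support. That fit took the 8 arrays with a common correlation of 0.543 within pairs, and 3948 probes passed in it.

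**Figure D1:**
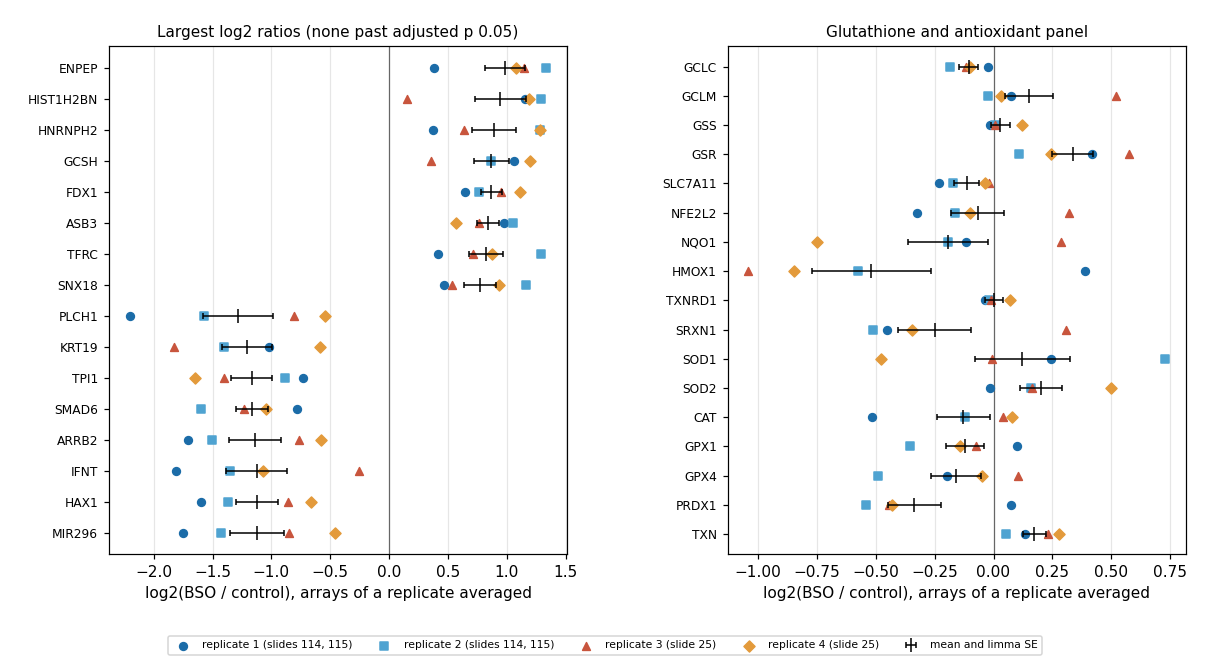
Log2 ratio of BSO over control for the 16 genes with the largest ratios (left) and for 17 glutathione and antioxidant genes (right). Each symbol is 1 replicate, the average of 2 arrays of opposite dye orientation, and the bar is the mean with its limma standard error; the 16 genes were chosen for 1 sign in all 4 replicates and the panel was not, and none of either passed the adjusted threshold.

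GCLC and GCLM, the catalytic and modifier subunits of the enzyme that BSO blocks, were at -0.11 ± 0.04 and 0.15 ± 0.10 (limma SE, n = 4), and GSS, the glutathione synthetase, at 0.030 ± 0.040. GCLC and GSS were dim, with mean log2 intensities of 7.35 and 7.23, where ratios are compressed. GSR, which reduces oxidized glutathione, had the highest ratio of the 17 panel genes, at 0.34 ± 0.09 and higher in 4 of 4 replicates, with a limma adjusted p of 0.128. PRDX1, a peroxiredoxin, was at -0.34 ± 0.11 and the thioredoxin TXN at 0.17 ± 0.05, with adjusted p of 0.188 and 0.151. HMOX1, the heme oxygenase induced by oxidative stress, was at -0.52 ± 0.25, but replicate 1 was at 0.39 and the others at -1.04 to -0.57. SOD2, the mitochondrial superoxide dismutase, was at 0.20 ± 0.09. The cystine transporter SLC7A11, at -0.11 ± 0.05, and SRXN1, at -0.25 ± 0.15, did not pass either, nor did NQO1 at -0.19 ± 0.17 and GPX1 at -0.12 ± 0.08. SOD1, at 0.12 ± 0.20, CAT, at -0.13 ± 0.11, GPX4, at -0.16 ± 0.11, and the regulator NFE2L2, at -0.067 ± 0.113, were of the opposite sign in replicates 3 and 4 alone, at -0.24, 0.059, 0.026 and 0.11. TXNRD1 was at 0.0012 ± 0.0371, but its brightest probe lay at 85.2% or more of the array maximum, where the scale limits ratios.

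Trophectoderm markers were the list with the lowest median. The median of the 29 measured members was -0.28, with 23 below 0, and replicate medians were -0.11, -0.47, -0.16 and -0.24. Camera gave an adjusted p of 0.00138 over the 25 lists, but 0.800 with an estimated inter-gene correlation, and fry gave an adjusted p of 0.141. The estimated correlation was 0.049, and camera with it gave an unadjusted p of 0.0593. At an unadjusted p under 0.05, 11 members were lower and 1, ELF5, was higher, and 0 passed over all probes. Over all 13678 genes, 2025 were lower and 1425 higher at that p. Counts of list members, here and below, were not tested against these shares. Adjusted over the list alone, 6 passed, all lower: the transcription factors DLX3, at -0.58 ± 0.08, and HAND1, at -0.19 ± 0.05; the trophoblast Kunitz domain proteins TKDP2, at -0.73 ± 0.11, and TKDP1, at -1.07 ± 0.19; KRT19; and IFNT (limma SE, n = 4). The lineage regulators CDX2, GATA3 and EOMES, at 0.0074, -0.046 and 0.13, did not pass, at mean log2 intensities of 7.54, 7.93 and 7.20. Among markers of the other cell types, the median was -0.044 for 20 epiblast and pluripotency genes and -0.049 for 23 hypoblast genes, with adjusted p of 0.714 for both, and the difference between these lists and the trophectoderm list was not tested. The trophectoderm median was -0.31 in replicates 1 and 2 and -0.20 in replicates 3 and 4, which lay on other slides, with adjusted p of 0.00643 and 0.000833. Exchanging BSO and control within replicates makes 8 assignments of the pools, and 6 of them, the real one included, gave at least 2 lists past the threshold, with 6 lists at most. The trophectoderm list itself passed in 2 of the other assignments with camera. The adjusted p was 0.00760 with replicate 3 exchanged, where the list was lower. It was 0.00153 with replicates 2, 3 and 4 exchanged, where the list was higher. The latter is the same split as exchanging replicate 1 alone, with every sign turned, and there the list is lower.

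**Figure D2:**
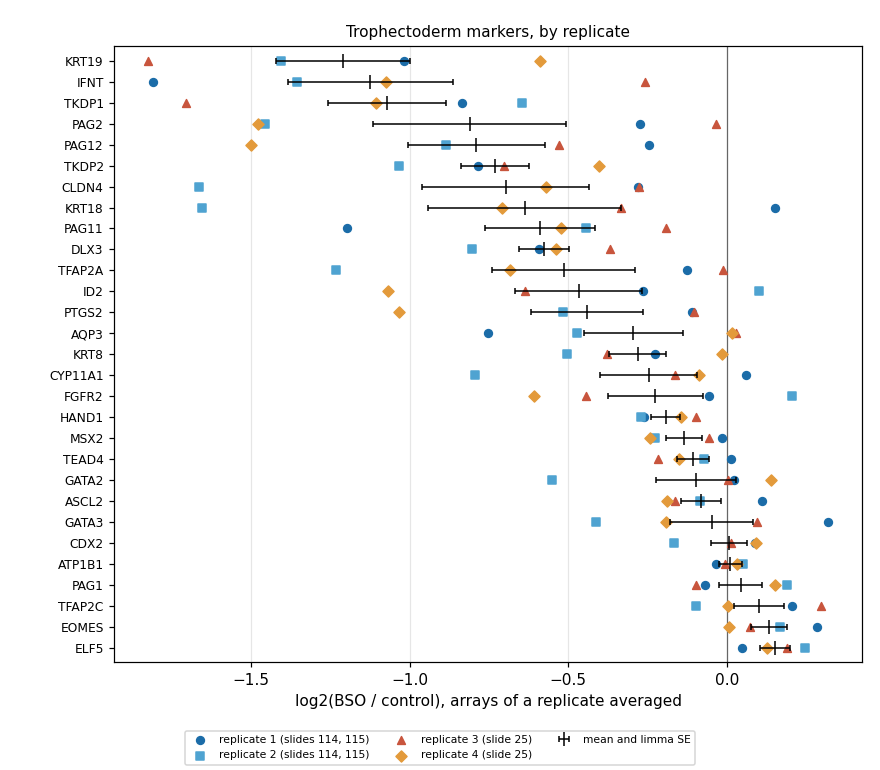
Log2 ratio of BSO over control for the 29 trophectoderm markers measured, in order of their mean. Each symbol is 1 replicate, and the bar is the mean with its limma standard error; the means run from -1.21 for KRT19 to 0.15 for ELF5, and 23 of the 29 lie below 0.

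Transcripts of the ribosomal proteins were lower by a small amount. The median of 67 genes was -0.087, with 48 below 0, and camera gave an adjusted p of 0.00527, against an adjusted p of 0.800 with an estimated correlation and 0.349 with fry. At an unadjusted p under 0.05, 19 were lower and 2 higher, and adjusted over the list alone 11 were lower and 2 higher. All 67 genes passed the stricter filter, at 2 times the negative controls. Of the 14270 probes past that filter, 35.6% were at an unadjusted p under 0.05, 3066 lower and 2017 higher. Being at that p was thus no more common in the list than among bright probes. RPL35 was at -0.69 ± 0.05, RPL31 at -0.27 ± 0.03 and RPL24 at -0.29 ± 0.04, while RPL26 was at 0.20 ± 0.04 (limma SE, n = 4). Replicate 2 had the lowest median, -0.26, and replicate 1 was at 0.032. Without replicate 2 the adjusted p was 0.209. It was 0.115 in replicates 1 and 2 alone and 0.000833 in replicates 3 and 4 alone. The call was also lost without background correction, at 0.0653, and with the stricter filter on dim probes, at 0.114.

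The lists closest to glutathione depletion and oxidative stress did not pass with camera. Glutathione synthesis and use, with 41 genes, had a median of -0.063 and an adjusted p of 0.252, with 10 members lower and 4 higher at an unadjusted p under 0.05. Its only member past adjustment over the list alone was CHAC1, which degrades glutathione, at -0.78 ± 0.11. GPX3, CTH and the glutathione transferase GSTM1 were at -0.29, -0.39 and -0.59. The NRF2 pathway and its targets, with 25 genes, had a median of -0.14 and an adjusted p of 0.137, and 0 members passed over the list alone. Among them, the autophagy receptor SQSTM1 was at -0.55 ± 0.11, AKR1B1 at -0.49 ± 0.10 and PGD, of the pentose phosphate pathway, at -0.45 ± 0.10. Superoxide and peroxide removal, with 24 genes, had a median of -0.043 and an adjusted p of 0.714, and its peroxiredoxin PRDX2 passed over the list alone, at -0.62 ± 0.10. Other members were SESN3 at 0.21, TXN2 at -0.30 and TXNRD2 at -0.28. The endoplasmic reticulum and integrated stress response, with 29 genes, had a median of -0.098 and an adjusted p of 0.183. CHAC1 alone passed there, and CALR, ASNS and ATF4 were at -0.54, -0.75 and -0.35. Heat shock proteins, with 18 genes, had a median of -0.042 and an adjusted p of 0.517. HSP90AB1, at -0.56 ± 0.07, and the mitochondrial chaperone HSPA9, at 0.46 ± 0.08, passed over the list alone in opposite directions, while HSPB8 was at -0.71 and HSF2 at -0.14.

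Metal handling had the highest median of the 25 lists, 0.060 over 14 genes, with a camera adjusted p of 0.423. Adjusted over the list alone, the iron-uptake receptor TFRC, at 0.82 ± 0.15, and IREB2, an iron-sensing RNA-binding protein, at 0.75 ± 0.13, were higher, and the metallothionein MT1A, at -0.82 ± 0.12, was lower (limma SE, n = 4). The iron exporter SLC40A1 was at 0.27.

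In energy metabolism, glycolysis had 22 genes with a median of -0.091 and an adjusted p of 0.251. TPI1 and the aldolase ALDOA, at -0.90 ± 0.16, passed over the list alone, and ENO1 and the glucose transporter SLC2A1 were at -0.80 and -0.32. Nuclear genes of oxidative phosphorylation, 75 in number, had a median of -0.046 and an adjusted p of 0.423, with 19 lower and 9 higher at an unadjusted p under 0.05. Over the list alone, COX4I1, at -0.62 ± 0.05, and NDUFB11, at -0.84 ± 0.15, were lower, while NDUFB5, at 0.59 ± 0.06, NDUFA5, at 0.54 ± 0.09, and SDHD, at 0.41 ± 0.08, were higher. Fatty acid and triglyceride synthesis, with 27 genes, had a median of -0.0027 and an adjusted p of 0.423. Over the list alone 4 of its genes were lower, among them the lipid-gene regulator SREBF1, at -0.41 ± 0.04, the fatty acid carrier FABP5, at -0.42 ± 0.04, and ELOVL1, at -0.91 ± 0.18, and 2 were higher, among them ELOVL5, at 0.55 ± 0.06. Fatty acid oxidation, with 22 genes, had a median of -0.017, a mean of -0.012 and an adjusted p of 0.845, while its test pointed up. HADHB, at 0.43 ± 0.05, and ETFA, at 0.31 ± 0.06, passed over the list alone, and ETFDH and ACADS were at 0.39 and -0.13. Cholesterol synthesis, with 21 genes, had a median of -0.14, an adjusted p of 0.289 and 0 members past adjustment over the list alone. Its TM7SF2 was at -0.54, EBP at -0.30, STARD4 at -0.093 and HMGCS1 at -0.52, and replicate medians ranged from -0.28 to 0.12. Hypoxia-inducible genes, 21 in number, had a median of -0.0026 and an adjusted p of 0.517. Carbonic anhydrase CA9, at -0.46 ± 0.05, passed over the list alone, and ERO1A was at 0.46 and BNIP3 at -0.16.

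**Figure D3:**
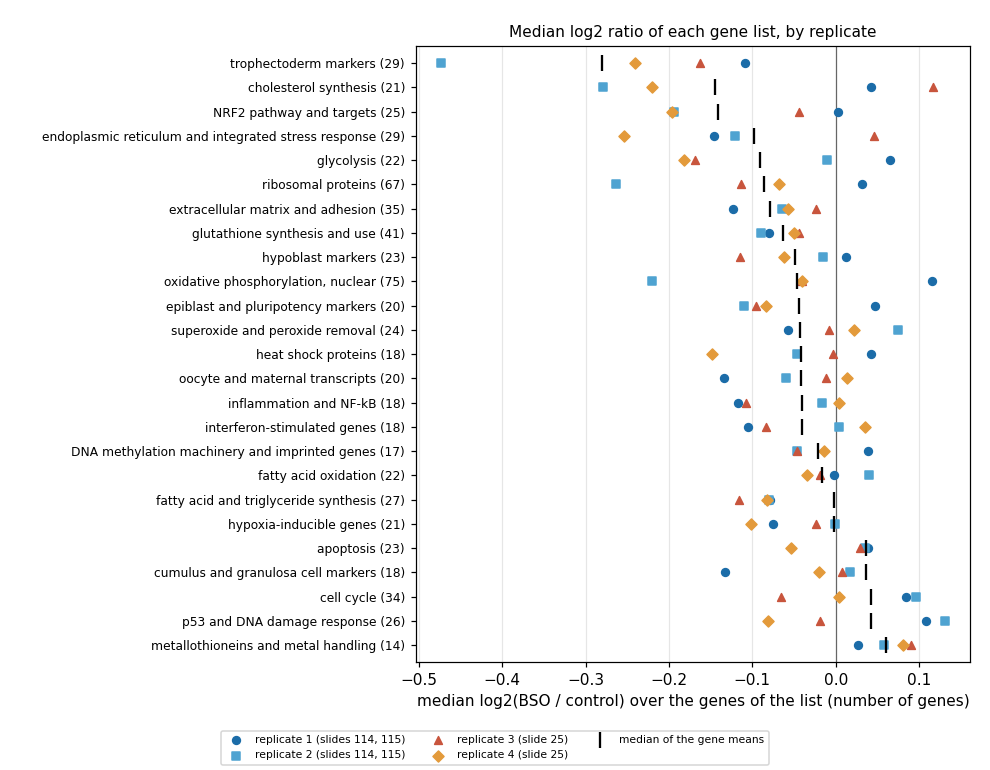
Median log2 ratio of BSO over control of each of the 25 gene lists, with the number of genes measured in parentheses. Each symbol is the median in 1 replicate and the black mark is the median of the gene means; trophectoderm markers lie at -0.28 and below 0 in all 4 replicates, and the highest list, metallothioneins and metal handling, lies at 0.060.

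Proliferation genes had ratios of both signs. The cell cycle list, with 34 genes, had a median of 0.042 and a camera adjusted p of 0.612. Over the list alone 6 members were higher, among them CCNE2, at 0.41 ± 0.06, and the kinetochore protein CENPF, at 0.64 ± 0.09, and 4 were lower, among them CCNB2, at -0.37 ± 0.05, and the mitotic activator CDC20, at -0.32 ± 0.05 (limma SE, n = 4). The p53 and DNA damage response, with 26 genes, had a median of 0.042 and an adjusted p of 0.714. The checkpoint kinases ATR, at 0.38 ± 0.06, and ATM, at 0.40 ± 0.08, were higher over the list alone and PLK3, at -0.42 ± 0.07, was lower, and MDM2 was at 0.21. Apoptosis genes, 23 in number, had a median of 0.037, a mean of -0.019 and an adjusted p of 0.714, with 0 members past adjustment over the list alone. DIABLO was at 0.18, BCL2L11 at -0.26, BNIP3 at -0.16 and BID at -0.27.

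In the epiblast and pluripotency list, KLF5, at 0.30 ± 0.05, DPPA3, at 0.49 ± 0.09, and SPIC, at 0.58 ± 0.12, were higher over the list alone, and SALL4, at -0.18 ± 0.04, NODAL, at -0.31 ± 0.08, and FGF4, at -0.17 ± 0.05, were lower (limma SE, n = 4). In the hypoblast list, LAMA1 was at -0.42, the regulator GATA4 at -0.85 ± 0.17, LAMB1 at 0.26 and APOA2 at -0.13, and 0 passed over the list alone. Cumulus and granulosa cell markers, 18 in number, had a median of 0.037, a mean of 0.0079 and a camera adjusted p of 0.792, while the test pointed down. FDX1 passed over that list alone, and NR5A1, FST and FSHR were at -0.25, -0.16 and -0.24. Oocyte and maternal transcripts, 20 in number, had a median of -0.042 and an adjusted p of 0.423, with TLE6 at -0.47, NOBOX at -0.20, H1-8 at -0.18 and WEE2 at -0.15. Extracellular matrix and adhesion genes, 35 in number, had a median of -0.079 and an adjusted p of 0.183. The tight-junction protein CLDN6, at -0.60 ± 0.08, passed over the list alone, and ANXA2 was at -0.87, SPP1 at 0.57 and JUP at -0.22. Inflammation and NF-kB genes, 18 in number, had a median of -0.040 and an adjusted p of 0.423, with RELA at -0.23, NFKB1 at -0.32, NFKB2 at -0.53 and ICAM1 at -0.20. Interferon-stimulated genes, 18 in number, had a median of -0.040 and an adjusted p of 0.517, with IFIT2 at 0.14, MX2 at -0.13, EIF2AK2 at -0.26 and IRF7 at -0.58. The DNA methylation and imprinting list, with 17 genes, had a median of -0.021 and an adjusted p of 0.723. The imprinted gene SNRPN passed over the list alone, at -0.56 ± 0.10, and DNMT3B was at -0.53 ± 0.25, DNMT3L at 0.067 and PEG10 at 0.076, the last of them at -0.042 in replicates 3 and 4 alone.

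With an estimated inter-gene correlation, 0 of the 25 lists passed, at adjusted p of 0.800 to 0.844. That version of camera has few residual degrees of freedom with 4 replicates, so it has little power here. The number past the threshold with camera was 2 in the 4 replicates and between 1 and 5 when 1 replicate was left out: 4 without replicate 1, 1 without replicate 2 and 5 without replicate 3.

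The dye swap was needed. A dye effect passed an adjusted p of 0.05 for 8431 probes in the fit with a treatment and a dye term. Averaging arrays of opposite orientation cancels such an effect in the BSO ratio, yet BSO and dye effects correlated at 0.344 across probes, which are not independent replicates. Both effects come from the same arrays, and a positive correlation goes by arithmetic with smaller ratios where BSO was in Cy3. Ratios were smaller where BSO was in Cy3, with SDs over probes of 0.345, 0.363, 0.172 and 0.316 in replicates 1 to 4, against 0.379, 0.436, 0.340 and 0.340 where BSO was in Cy5.

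The slides make 2 technical sets of 2 replicates each. The BSO effect differed between them for 0 probes with limma at an adjusted p of 0.05, with a lowest adjusted p of 0.714, and 2541 probes had an unadjusted p under 0.05. In the fit of the 8 arrays with a dye term, 170 probes differed. Effects in the sets correlated at 0.509 across probes. Within the set of replicates 1 and 2 there were 5277 probes at an unadjusted p under 0.05, and within that of replicates 3 and 4 there were 5881, with 0 past the adjusted threshold in either.

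The deposited log2 values, tested in the same way, gave 220 probes past the adjusted threshold, 97 higher and 123 lower, with 9606 at an unadjusted p under 0.05. Their log2 ratios correlated with those computed here at 0.994 across the 36995 probes. Of the deposited probes at an unadjusted p under 0.05, 48.6% were higher.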

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

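The trophectoderm and ribosomal tests on the dye profile, the test of cell share, the test of brightness and both tests of the link between BSO and dye effects were chosen only after the result was seen, while the family test and the tests of chance were written before, except that the test of chance for the dye effect was narrowed to fewer splits afterwards.

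In replicates, 5 of 58 groups of 4 values held an outlying replicate, against 2.9 expected, and chance gives about 1 in 20 groups. HIST1H2BN was at 0.153 in replicate 3 and at 1.15 to 1.29 in the others. GSS was at 0.120 in replicate 4 and at -0.013 to 0.0070 in the others. The median of the fatty acid and triglyceride synthesis list was -0.116 in replicate 3 and -0.083 to -0.078 in the others. The median of the epiblast and pluripotency list was 0.047 in replicate 1 and -0.11 to -0.084 in the others. The median of the apoptosis list was -0.054 in replicate 4 and 0.029 to 0.039 in the others.

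The trophectoderm markers were lower, and 3 explanations were tested. Dye bias left after the swap would have raised the adjusted p to 0.05 or more once the dye profile was regressed out. It was 0.00059, but that subtraction is largely shared by the replicates and can itself move a list, so this cannot decide. Dye bias alone would give the orientations opposite signs. The list median was -0.24 with BSO in Cy5 and -0.35 with BSO in Cy3, which goes against dye bias alone. Cross-hybridisation among the IFNT, PAG and TKDP families could explain part of it: without them 22 genes were left, with a median of -0.21 and an adjusted p of 0.0429, so the prediction against this cause, written before, was met, but leaving out 1 replicate gave 0.00933 to 0.209 and the question stays open. For a lower share of trophectoderm cells, the prediction was a rise of epiblast and hypoblast markers by the size of the trophectoderm fall. That size was 0.455 (interval 0.087 to 0.823) in markers past the stricter filter. The upper 95% limit of the mean replicate median of the other markers was 0.204, below 0.455 but inside that interval. The rise that a lower share needs depends on the starting share of cells, which was not measured, so this could not be told either. Conditions on the replicates left out and on the overlap of intervals were added after the values of these last 2 tests were seen. The sum of both medians, -0.48 (-0.89 to -0.068), was also computed afterwards and rests on the same assumption of equal sizes.

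BSO and dye effects moved together over probes, at a correlation of 0.344. If dye bias left after the swap made the probes at an unadjusted p under 0.05, regressing out the dye profile would lower their number. It was 9977 against 8297. The profile came from the other replicates, so a largely shared profile was subtracted from all 4, with slopes of 0.223 to 0.560. Such a subtraction can itself raise the count, so the rise cannot decide. Smaller ratios in arrays with BSO in Cy3 were found in 4 of 4 matched pairs, by SD, but this largely restates the correlation. The BSO effect is the mean of both orientations and the dye effect comes from their difference. A positive correlation therefore requires a smaller spread over probes of the ratios averaged over arrays with BSO in Cy3. It does not require this in every pair. Why the ratios were smaller stays open.

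The ribosomal proteins were lower by a median of -0.087. Dye bias would have raised the adjusted p to 0.05 or more, and it was 0.000611 with the dye profile regressed out. As that subtraction can itself move a list, this cannot decide. A bias that depends on brightness would have put the list median well inside the spread of random lists of the same brightness, and it lay at percentile 0.32. Trophectoderm markers lay at percentile 0. Among lists that did not pass with camera, 4 also had low percentiles: the NRF2 pathway at 0.81, cholesterol synthesis at 0.97, extracellular matrix at 1.12 and the endoplasmic reticulum stress response at 1.69. The random lists take genes as independent, while the estimated correlation between these genes was 0.391, and with it the adjusted p was 0.800. With the filter at 2 times the negative controls all 67 genes stayed, and camera gave an adjusted p of 0.114. The median over all kept probes was then -0.033, against 0.0079 before. A bias that depends on brightness therefore stays open.

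For chance, 1 of 8 assignments of the pools, the real one, gave as many probes at an unadjusted p under 0.05, with 8297 against 2687 at most in the others, but 8 assignments are too few for a share under 5%. For lists past the threshold, 6 of 8 assignments gave at least 2, and the highest other gave 6. The real count of 2 lay below that of 4 of the other assignments, so it did not stand out from them. For the dye effect, 1 of the 8 splits of the arrays that part all 4 matched pairs, the real one, gave as many probes, with 8431 against 0 at most in the others, and these are too few for a share under 5%. As written before, the test took all 35 splits of the arrays into 4 and 4, of which the real one alone gave as many, with 319 at most in the others. It was narrowed after these values were seen, because arrays of a matched pair are not independent, and the matching itself was inferred from the data.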

How the results depend on the processing

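The stricter filter, the negative-control background, the threshold of 0.10 and the regression on the dye profile were chosen only after the result was seen, and the other alternatives were set earlier. In each case the cause was not tested.

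For BSO against control, 0 probes passed. Without background correction 468 passed, 139 higher and 329 lower, and with the negative-control background 545, 133 higher and 412 lower. Without the filter on dim probes 91 passed, 28 higher and 63 lower, and with the filter at 2 times the negative controls 250, 58 higher and 192 lower. With 8 arrays as independent 7011 passed, with the matched pair as replicate block 3948, and with array weights 356. Taking 8 arrays as independent counts arrays that share pools as separate replicates. Its counts, here and below, are therefore not equally valid outcomes. The deposited table gave 220. The 24 matchings gave a median of 5096 and at most 9304, and the matching used gave 0. Other matchings average arrays with opposed deviations, which shrinks the spread between averages. At an unadjusted p under 0.05 with a 1.5-fold difference 621 passed, and at an adjusted p under 0.10 there were 2147, 721 higher and 1426 lower. The lowest adjusted p was 0.0514, and 0.252 with trend and robust. The count was 0 with each replicate left out, with offset 10, median centring, a slide block, and trend and robust.

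At an unadjusted p under 0.05, 8297 probes became 12589 with 8 arrays as independent, 5277 in replicates 1 and 2 alone, 4045 of 14270 with the filter at 2 times the negative controls, and 14062 at most over the 24 matchings. With replicates left out the range was 5739 to 7764. The higher share was 38.6%, against 49.0% with median centring, 48.6% in the deposited table and 47.1% with the dye profile regressed out.

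Of the gene lists, 2 passed. This became 1 without background correction, 1 in replicates 1 and 2 alone, 1 with the filter at 2 times the negative controls, 0 with an estimated correlation and 0 with fry. With replicates left out it ran from 1 (without replicate 2) to 5 (without replicate 3). The panel count of 0 became 3 with 8 arrays as independent. Counts of list members moved in 56 cases and stayed in 450.

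For trophectoderm markers, the adjusted p of 0.00138 was lost with an estimated correlation, at 0.800, and with fry, at 0.141. With replicates left out it was 0.000266 to 0.00687. For ribosomal proteins, 0.00527 became 0.0653 without background correction, 0.115 in replicates 1 and 2 alone, 0.114 with the filter at 2 times the negative controls, 0.800 with an estimated correlation and 0.349 with fry. With replicates left out it was 5.24e-06 to 0.209, the highest without replicate 2. The BSO effect differed between slide sets for 0 probes, and for 170 in 8 arrays with a dye term.

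Some genes near 0 changed sign. GSS was -0.0031 in replicates 1 and 2 alone and -0.0085 with the dye profile regressed out, and ran from -0.00041 to 0.044 with replicates left out. NFE2L2 was 0.11 in replicates 3 and 4 alone and 0.010 with array weights, and ran from -0.20 to 0.018. TXNRD1 was -0.0012 with offset 10, -0.028 in replicates 1 and 2 alone, -1.56e-05 with the negative-control background and -0.012 with the dye profile regressed out, and ran from -0.022 to 0.014. SOD1 was -0.24 in replicates 3 and 4 alone and ran from -0.080 to 0.32. In replicates 3 and 4 alone CAT was 0.059, GPX4 0.026 and PEG10 -0.042, and PEG10 was -0.028 with the negative-control background. Signal over background limits dim probes, whose spots hold background that is not transcript, so their ratios are compressed. Of these genes, GSS and PEG10 were dim, with mean log2 intensities of 7.23 and 7.06, and the others were at 11.3 to 15.1.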

Other observations

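The looks at second probes, families of symbols, neighbours of PLCH1 and the top of the scale were chosen only after the result was seen.

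Among bright trophectoderm markers, the pregnancy-associated glycoprotein PAG2 was at -0.81, the tight-junction protein CLDN4 at -0.70 and the keratin KRT18 at -0.64. The transcription factor TFAP2A was at -0.51, ID2 at -0.47 and PTGS2 at -0.44, while GATA2 was at -0.096 and TFAP2C at 0.10. None of them passed over all probes. The median of the 20 bright markers was -0.54.

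Families of genes that share the start of a symbol were tested with camera for 87 families of at least 15 genes, and 0 passed. The lowest p belonged to RPL, 39 genes with a median of -0.12 and an adjusted p of 0.138. TAF, 19 genes that include subunits of the general transcription factor TFIID, had a median of 0.096 and an adjusted p of 0.209, with 6 members higher and 0 lower at an unadjusted p under 0.05. RPS, with 33 genes, had a median of -0.068 and an adjusted p of 0.209.

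A second probe of a gene often gave another ratio. Over 3400 genes with at least 2 probes the correlation of the first and second probe was 0.317, with 58.4% of the same sign. For 432 genes whose brightest probe had an unadjusted p under 0.01 it was 0.465, with 69.4% of the same sign. For 193 such genes with both probes bright it was 0.595, with 77.7% of the same sign. Values of genes with a single probe rest on that probe alone.

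At an unadjusted p under 0.05 there were 23.5% of named probes, 21.3% of unnamed probes and 35.6% of the 14270 bright probes, all by the fit over the 36995 kept probes, while a fit to the bright probes alone gave 4045 of them. Both dye orientations gave the same sign for 50.9% of kept probes, and without any BSO or dye effect chance gives 1 in 2. A dye effect, which passed for 8431 probes, sets the signs apart, so 1 in 2 is no baseline here. Of probes at an unadjusted p under 0.05, which are chosen on the mean of both orientations, 83.25% had the same sign. PLCH1 had 7 probes within a distance of 0.45 over the arrays, and the 473 lower probes had a median of 322 such neighbours. This distance compares the size of ratios as well as their pattern, and PLCH1 had the lowest ratio of the genes named. The count therefore cannot tell whether other probes share its pattern at a smaller size. At 80% or more of the array maximum on all arrays there were 62 probes, with a highest absolute log2 ratio of 0.11.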
